A study of Mus musculus with 48 samples.

How the data were processed

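RNA was measured in quadriceps, tibialis anterior, gastrocnemius and diaphragm of C57BL/6 mice at postnatal day 0, with 6 libraries labelled wild type and 6 labelled as Myh3 knockout per muscle. Per the labels the muscles were flash frozen, RNA was taken with a lipid tissue kit and libraries were made with the Illumina stranded mRNA kit after oligo dT selection. The processing notes of the submitters name Picard and the build mm10. The deposited tables are USeq output for 1 comparison per muscle, and their headers name the same build. The aligner is not given in the sources used here.

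Per the file headers the deposited counts are raw alignments over the exons of each gene, with the mates of a pair counted once. The log2 ratios are those of the authors, from DESeq2, for knockout over wild type, with a second set for the exon that changed most. The adjusted p-values were deposited as a score of -10 times log10 and were turned back into p-values. Columns of other kinds in the deposited tables gave exonic base pairs and the identifiers of genes that the authors left out. The authors left out genes with under 10 counts and genes flagged for high counts. The last flag took Acta1 from the quadriceps, tibialis anterior and diaphragm tables, H19 and mt-Co1 from quadriceps and diaphragm, and Mylpf from quadriceps. A gene that was kept had 927833 counts in knockout column 4 of tibialis anterior, above the limit in the header. The flag was therefore not a plain limit on counts per gene, and other abundant genes remain. The tables held 16090 genes for quadriceps, 15821 for tibialis anterior, 16097 for gastrocnemius and 16686 for diaphragm, and 1 line without values in each was dropped. Another 96 columns, which hold the authors' regularised log values and FPKM of each of the 48 samples, were not used. Start positions were raised by 1 for printing. Of the 17490 genes in the tables, 17262 are in GENCODE M21, and of these 17257 overlap the annotated gene on the same chromosome.

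Libraries were grouped by the genotype and muscle in the column headers and the labels. The 6 columns of a group carry the numbers 0 to 5, which the sources do not tie to replicate numbers, so no pairing by animal was possible. Total counts per library ran from 11.9 M to 24.3 M (median 16.1 M), with medians of 12.9 M (knockout) and 13.0 M (wild type) in diaphragm, 15.9 and 15.9 in gastrocnemius, 17.7 and 17.6 in quadriceps and 16.8 and 16.2 in tibialis anterior. The 20 genes with the most counts took 16.2% to 25.1% of a library. Replicates were checked for copies: the chi-square per degree of freedom between libraries of a group ran from 5.33 to 78.7 over 120 pairs, so none were repeats of 1 library.

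Counts were fitted in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM factors, quasi-likelihood F test) in each muscle as knockout against wild type, with Benjamini-Hochberg adjustment at 0.05. Standard errors are the absolute log2 change over the root of F. Joint fits of all 48 libraries tested whether the effect was equal in the 4 muscles and, with muscle as a term, the effect shared by them; a sum over the muscles of each animal had been chosen first but needs replicate numbers. Fits of the 24 wild-type libraries compared the diaphragm with the mean of the limb muscles (at least 2-fold) and the limb muscles with one another. Effects were correlated across genes between muscles and set beside 100 permutations. Every fit was first tested on simulated data with genes changed 1.5-, 2- and 3-fold.

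Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with the preset correlation of 0.01, with Myh3 left out of every list and adjustment over the 26 lists of a muscle. They were fixed before the data were examined and cover fast and slow fibre genes, other sarcomeric myosins, developmental isoforms, progenitors, differentiation and fusion, proliferation, FGF and MAPK feedback, immediate early genes, stress and atrophy, the neuromuscular junction, glycolysis, oxidative phosphorylation, fibroblasts, tendon, cartilage and bone, endothelium, macrophages, erythroid cells, Schwann cells, adipocytes, liver, mesothelium, skin, and posterior and anterior Hox genes. The comparisons, tests, most alternatives and the rule for naming genes were also fixed before the data were examined. The rule named Myh3, the genes past 0.05 with the smallest p (up to 12 in each direction), up to 5 next genes by p where fewer than 10 passed in a direction, up to 4 members of each list that passed and of the muscle lists, and every gene on the authors' short lists, with predicted genes passed over. In the joint fits it named up to 10 genes in each direction, and in the wild-type fits up to 12 in each direction with the largest fold and up to 4 members of each list. The values of Alb per library, further genes that passed when adjusted over a list alone, and the wild-type levels of Mapt were named after they were seen.

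Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma voom with sample quality weights, no filter or at least 1 CPM in at least 6 libraries, all 48 libraries in 1 fit, adjustment at 0.10 alone and with the authors' minimum change, a covariate of sex-linked expression, 1 surrogate variable from sva 3.50.0, abundant genes left out, camera with an estimated correlation, fry, and each library left out in turn. Leaving out knockout columns 0 and 1 was added after these libraries were seen to stand apart, and so were 2 lists, of genes that rise on fasting and of heart genes. Fits that need pairs of samples were not run.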

Results

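Gene counts of 4 neonatal mouse muscles were compared between libraries labelled knockout (KO) and wild type (WT) for Myh3, the gene of embryonic myosin heavy chain, to ask which genes change in each muscle when it is lost. The muscles were quadriceps (Quad), tibialis anterior (TA), gastrocnemius (Gastroc) and diaphragm (Dia), with 6 libraries per genotype and muscle and 48 in all. Single libraries are named by genotype and by the number of their count column, from 0 to 5. The labels do not say which replicate or animal stands behind a column, so the muscles of 1 animal could not be paired. The p-values of the gene tests in each muscle measure the spread between samples. Those of camera set a list against the other genes and depend on the correlation used. Changes are log2 fold changes of KO over WT ± SE from edgeR, levels are library-scaled counts (CPM) ± SD with n = 6, and adjusted p-values are Benjamini-Hochberg values over all genes tested in that comparison.

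Counts of Myh3 itself did not pass the edgeR test in any of the 4 muscles. The gene lies on chromosome 11 from 67078300 to 67102291 (mm10, plus strand). In Quad it was at 4629 ± 610 CPM in KO and 4638 ± 660 CPM in WT, a log2 change of -0.00 (adjusted p = 0.999; 3 of 6 KO samples above the WT median). In TA it was at 3245 ± 357 CPM in KO and 4195 ± 506 CPM in WT, a log2 change of -0.37 ± 0.09 (adjusted p = 0.183), and all 6 KO samples lay below the WT median. In Gastroc the levels were 4760 ± 437 and 4373 ± 443 CPM (0.12 ± 0.08, adjusted p = 0.902; 4 of 6 KO samples above the WT median), and in Dia 1561 ± 397 and 1133 ± 293 CPM (0.46 ± 0.20, adjusted p = 0.9996; 5 of 6 above). With DESeq2 the adjusted p in TA was 0.0368, in the authors' own table it was 0.0406, and over the alternatives with all 6 libraries it ran from 0.0368 to 0.446. Without KO columns 0 and 1 the value in Dia was 0.25 (adjusted p = 0.629). The labels do not say which part of Myh3 was deleted and counts are per gene, so they do not check the genotype of any library.

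**Figure D1:**
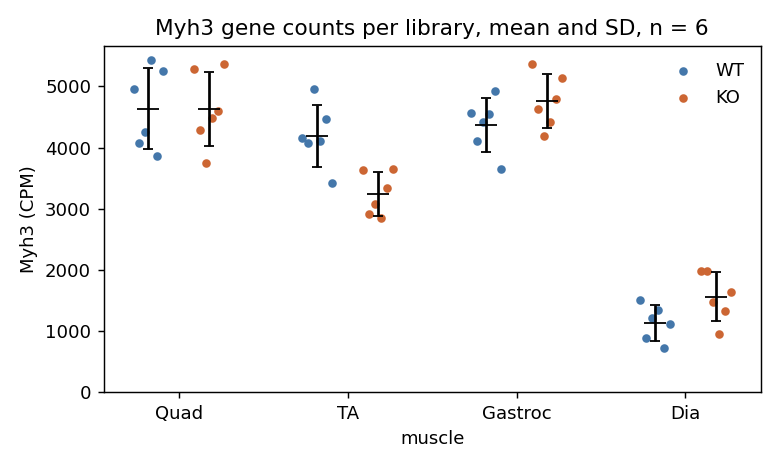
Normalised read count of Myh3 (CPM) in each library by muscle and genotype, with the mean and SD of 6 libraries. The KO and WT libraries overlapped in all 4 muscles, and the means in TA were 3245 CPM in KO and 4195 CPM in WT.

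In Quad no single gene passed. Among the genes with the smallest p-values, given as values that did not pass, Myl2, Myl3 and Tpm3 of the slow fibre list had negative changes. Csrp3, which is in the slow fibre and the stress list, Trim63 of the stress list, Btg2 of the immediate early list, Ppargc1a of the oxidative list, and Shisa3 and Adamts15, which are in no list, had positive changes. By list, immediate early and stress genes had the smallest p with the preset correlation. None of 14710 genes passed edgeR at an adjusted p of 0.05, while 1020 had an unadjusted p under 0.05; DESeq2 called 71 genes, limma voom with sample quality weights 16, and 72 had an adjusted p under 0.05 in the authors' own DESeq2 results. Myl2 (chromosome 5, 122100951 to 122113472) was at 105 ± 26.2 CPM in KO and 234 ± 55.1 CPM in WT, a log2 change of -1.15 ± 0.17 (adjusted p = 0.0568; 0 of 6 KO samples above the WT median). Shisa3 (1.12 ± 0.17), Myl3 (-0.998 ± 0.161), Csrp3 (1.14 ± 0.19; 573 against 260 CPM), Ppargc1a (0.76 ± 0.12) and Btg2 (0.87 ± 0.14) had the same adjusted p, and each had all 6 KO samples on one side of the WT median. Adamts15 (0.70, adjusted p = 0.0728), Tpm3 (-0.55) and Trim63 (1.27 ± 0.23, adjusted p = 0.0764) followed. Without KO column 0, KO column 4 or WT column 1 the count was 2, and without KO column 5 or WT column 3 it was 1. In tests on simulated data the same fit found 82.1% of genes changed 2-fold and 43.3% of those changed 1.5-fold. The simulated data had many changed genes at once and no structure among the libraries of a group. These shares may therefore be too high for the real libraries, in which Myl2 did not pass.

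Of the 26 fixed lists, 7 passed camera with its preset correlation in Quad, and 0 passed with an estimated correlation; the lowest adjusted p was then 0.247. The immediate early list was higher (adjusted p = 3.51e-11, adjusted p = 0.247 with an estimated correlation), with all 19 measured members above 0 and 10 past the test adjusted over the list alone, among them Btg2, Dusp1, Nr4a1, Ctgf and Atf3. The muscle stress and atrophy list was higher (adjusted p = 1.49e-06, adjusted p = 0.247 with an estimated correlation), and Csrp3, Trim63, Ankrd1, Ankrd2 and Foxo1 passed when adjusted over the list alone. The slow fibre list was lower (adjusted p = 0.00839, adjusted p = 0.483 with an estimated correlation): adjusted over the list alone Myl2, Myl3, Tpm3, Tnnt1 and Tnnc1 fell, Csrp3 rose and 7 of 13 did not pass. The lists of developmental isoforms (adjusted p = 0.0376; Ankrd1 alone rose when adjusted over the list alone) and mesothelium (adjusted p = 0.00839; Msln rose) were higher. Those of endothelium (adjusted p = 0.0276; Cldn5 fell) and erythroid cells (adjusted p = 0.00587; no member passed) were lower. With an estimated correlation these 4 had adjusted p = 0.475, 0.247, 0.247 and 0.475. No member of any list passed over all genes.

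Leaving out 1 library ended several of these list calls. The slow fibre list had adjusted p = 0.0588 without KO column 1, 0.0575 without KO column 2 and 0.0619 without WT column 5. The developmental list had 0.185 and 0.111 without KO columns 0 and 1, and 0.159 and 0.0600 without WT columns 2 and 4. The endothelial list had 0.0684, 0.105 and 0.0575 without KO columns 0, 1 and 2 and 0.0820 without WT column 5, and the mesothelium list 0.0616 without KO column 0. Without both KO columns 0 and 1 all 5 of the calls other than immediate early and stress genes ended: slow fibre (0.0612), developmental (0.639), endothelial (0.285), erythroid (0.0527) and mesothelium (0.144), while fibroblast (0.00200) and proliferation genes (0.0221) were lower. The number of lists past the test was 4 without KO column 1, 12 without KO column 4 and 11 without WT column 3.

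The other 19 lists did not pass in Quad. Among muscle genes these were fast fibre (adjusted p = 0.457), other sarcomeric myosins (0.0853), progenitor (0.0853), differentiation and fusion (0.430), proliferation (0.538), FGF and MAPK feedback (0.116), neuromuscular junction (0.481), glycolysis (0.681) and oxidative phosphorylation genes (0.0853). Among other tissues they were fibroblast (0.179), tendon (0.114), cartilage and bone (0.0853), macrophage (0.0853), Schwann cell (0.991), adipocyte (0.0853), liver (0.906) and skin genes (0.637), and the posterior and anterior Hox lists had 0.179 each. Median, mean and test differed in sign for glycolysis, Schwann cell and skin genes. Pax7 (0.14, adjusted p = 0.950) and Myod1 (0.13, adjusted p = 0.977) did not pass either.

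Liver genes moved with single KO libraries rather than with the genotype. All 6 measured liver genes in Quad had a positive log2 change, with a median of 1.05, and without KO columns 0 and 1 the median was -1.21. Alb was at 27.6 and 48.9 CPM in these columns and at 0.209 to 6.29 CPM in the other KO libraries of Quad. The same columns carried 38.1 and 47.5 CPM of Alb in TA, 23.0 and 18.5 CPM in Gastroc, and 3569 and 5836 CPM in Dia. The median of the list changed from 0.98 to -1.09 in TA, from 0.33 to -1.47 in Gastroc and from 0.60 to -0.48 in Dia. In Dia WT column 1 also held 3033 CPM. KO columns 0 and 1 lay close together on the first 2 principal components of Quad, TA and Gastroc; in Dia both lay at the negative end of the first, beside WT column 1, and apart on the second. Without them 133 genes passed in Quad.

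**Figure D2:**
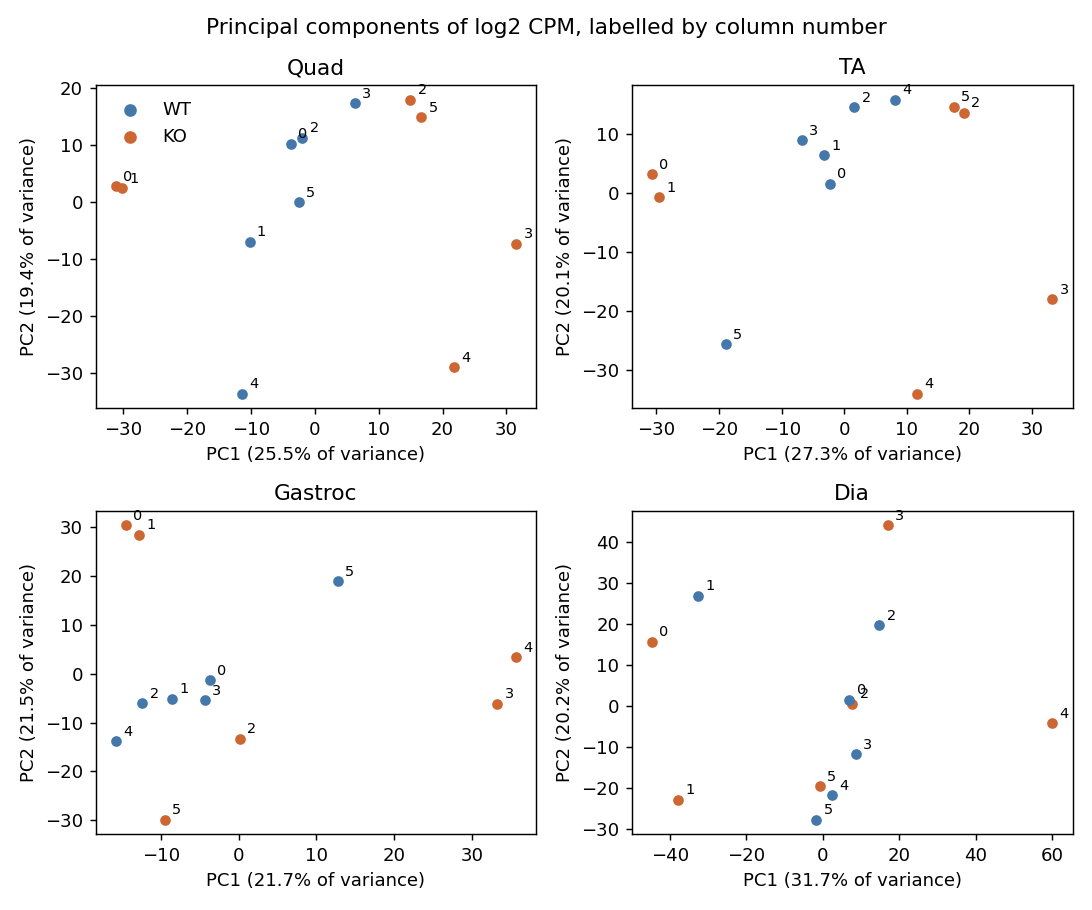
Principal components 1 and 2 of log2 CPM in each muscle (axes give the percent of variance), with points coloured by genotype and marked with their column number. KO columns 0 and 1 lay close together in Quad, TA and Gastroc, apart from the other 4 KO libraries.

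In TA the slow fibre genes fell as a group, and 8 genes outside the stress and immediate early lists rose. Myl2, Tnnc1, Myl3 and Tpm3 passed the test over all genes, with Car3 and Psat1, which are in no list, as the other genes that fell. The genes that rose were Mchr1, Mn1, Slc2a1, Pde4d, Lpin1, Klhl38, Usp2 and Mylk2. edgeR called 14 of 14383 genes, 8 higher and 6 lower, against 1091 with an unadjusted p under 0.05, and for each called gene the 6 KO samples did not overlap the 6 WT samples. Myl2 fell from 359 to 140 CPM, a log2 change of -1.36 ± 0.09 (adjusted p = 9.34e-07). Tnnc1 changed by -0.59 ± 0.07 (adjusted p = 0.00185), Car3 by -0.64 ± 0.08 (adjusted p = 0.00347), Myl3 by -0.84 ± 0.13 (adjusted p = 0.0177), Tpm3 by -0.46 ± 0.08 (adjusted p = 0.0353) and Psat1 by -0.51 ± 0.09 (adjusted p = 0.0398). Mchr1 had the smallest p among those that rose (1.09 ± 0.15, adjusted p = 0.00678), and Klhl38 had the largest change (1.52 ± 0.26, adjusted p = 0.0401). Lpin1 rose by 1.26, Pde4d by 0.99, Mn1 by 0.91 and Slc2a1 by 0.89, each with adjusted p = 0.0297, while Mylk2 rose by 0.75 (adjusted p = 0.0480) and Usp2 by 0.37. Myh7 (-0.51 ± 0.10, adjusted p = 0.0806), Fbxo32 (1.41 ± 0.32, adjusted p = 0.135), Trim63 (1.00, adjusted p = 0.138) and Asns (-0.66, adjusted p = 0.107) did not pass.

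Myl2, Tnnc1, Car3 and Mchr1 kept their calls in TA whichever library was left out. The number of called genes was 26 without KO column 0, 8 without KO column 1, 7 without KO column 3 and 9 without KO column 5. It was 4 without WT column 0, 1 or 2, 6 without WT column 3, 8 without WT column 4 and 5 without WT column 5. Myl3 had adjusted p = 0.0683, 0.0504 and 0.0728 without WT columns 0, 1 and 2. Of the 12 fits Usp2 kept its call in 1, Mylk2 and Tpm3 in 2, Psat1 in 3, Klhl38 in 4, and Lpin1, Mn1, Pde4d and Slc2a1 in 5, with adjusted p up to 0.140 for Usp2, 0.138 for Mylk2, 0.135 for Psat1 and Klhl38, 0.116 for the last 4 (all without WT column 2) and 0.0986 for Tpm3 (without WT column 3). With all 48 libraries in 1 fit Car3 (adjusted p = 0.0963), Slc2a1 (0.191), Mylk2 (0.211) and Usp2 (0.332) lost their calls. With a covariate of sex-linked expression Slc2a1 (0.0515), Klhl38 (0.0615), Tpm3 (0.0668), Psat1 (0.0755), Usp2 (0.0787) and Mylk2 (0.0982) lost theirs. DESeq2 called 117 genes, all 14 of these among them.

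The slow fibre list was lower in TA with the preset correlation (adjusted p = 3.03e-13) and with an estimated one (adjusted p = 0.00104). Of its 13 members 4 passed over all genes and 7 when adjusted over the list alone, which adds Myh7, Tnnt1 and Tnni1. Immediate early genes were higher (adjusted p = 0.000355, adjusted p = 0.592 with an estimated correlation), and Btg2 and Nr4a1 passed when adjusted over the list alone. Stress genes were also higher (adjusted p = 0.00460, adjusted p = 0.592 with an estimated correlation): adjusted over the list alone Trim63, Fbxo32, Foxo1, Foxo3 and Gadd45a rose and Ankrd23 fell. The stress call ended without KO column 3 (adjusted p = 0.0800). Without both KO columns 0 and 1 proliferation (9.26e-05), fibroblast (0.000170) and cartilage genes (0.0450) were lower and adipocyte genes higher (0.00859). The number of lists past the test was 5 without KO column 1, KO column 4 or WT column 4, 6 without KO column 5 or WT column 0, and 7 without KO column 0 or WT column 3. The other 23 lists did not pass; fibroblast genes came nearest (adjusted p = 0.0630). Median, mean and test differed in sign for progenitor, FGF feedback and oxidative phosphorylation genes. Mylk2 was the 1 fast fibre gene that passed over all genes, and the fast fibre list did not (adjusted p = 0.467).

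In Gastroc the called genes were mostly higher in KO. Ankrd2, Csrp3 and Ankrd1 of the stress list rose, beside the muscle genes Xirp2 and Hspb7, which are in no list, the fast myosin gene Myh2 and the regulators Cebpb, Runx2 and Trib1. edgeR called 23 of 14611 genes, 21 higher and 2 lower, against 979 with an unadjusted p under 0.05. Ankrd2 rose from 14.5 to 120 CPM, a log2 change of 3.05 ± 0.41 (adjusted p = 0.01003). Xirp2 rose by 1.41 ± 0.19 (adjusted p = 0.01003), Csrp3 by 0.96 ± 0.15 (249 to 485 CPM, adjusted p = 0.0184), Hspb7 by 0.82 ± 0.13 (adjusted p = 0.0148) and Ankrd1 by 1.65 ± 0.30 (adjusted p = 0.0410). Myh2 (chromosome 11, 67171027 to 67197517) rose from 44.7 to 114 CPM (1.35 ± 0.22, adjusted p = 0.0186). Over all genes it did not pass in Quad (0.73 ± 0.25, adjusted p = 0.488) or Dia (1.16 ± 0.35, adjusted p = 0.778). Adjusted over the list of other sarcomeric myosins alone it rose in both, while no member of that list rose so in TA. Mybpc3 (1.59), Mfsd2a (1.57), Mapt (1.12), Shisa3 (1.10), Runx2 (1.10), Cebpb (0.95), Rgcc (0.91), Tiam2 (0.76), Col22a1 (0.63) and Trib1 (0.60) also rose, as did 2 further genes. Ces5a (1.85 ± 0.25, adjusted p = 0.01003), Trim9 (1.94) and Calml3 (1.70) rose from low levels of 0.569, 1.32 and 0.464 CPM. The WT levels of Mybpc3, Mfsd2a and Runx2 were also low, at 0.744, 1.04 and 1.18 CPM. Efemp1 (-0.71 ± 0.11, adjusted p = 0.0148) and Cadm3 (-0.69 ± 0.12, adjusted p = 0.0291) fell. In each called gene all 6 KO samples lay on one side of the WT median.

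Ces5a, Ankrd2, Xirp2 and Col22a1 kept their calls in Gastroc whichever library was left out. The count was 4 without WT column 2, 11 without WT column 0 or 5 and 12 without WT column 4. Csrp3 had adjusted p = 0.0502, 0.0548, 0.0593 and 0.0559 without WT columns 2, 3, 4 and 5, and Myh2 had 0.0517 and 0.0728 without WT columns 0 and 2. Of the 12 fits Runx2 kept its call in 2, Ankrd1, Cadm3 and Calml3 in 3, Cebpb and Trim9 in 4, Mybpc3 and Trib1 in 6, and Mfsd2a and Tiam2 in 8. Their highest adjusted p was 0.143 for Runx2 and 0.110 for Cebpb (without WT column 0), 0.141 for Ankrd1 and 0.114 for Calml3 (without WT column 2), and 0.0880 for Cadm3 (without WT column 4). Efemp1, Hspb7, Mapt, Rgcc and Shisa3 had adjusted p = 0.0502 without WT column 2. With all 48 libraries in 1 fit Efemp1 (0.0518), Cadm3 (0.0802), Runx2 (0.211) and Calml3 (0.965) lost their calls, with the sex covariate Cadm3 (0.0511), Calml3 (0.0547), Runx2 (0.0547) and 1 further gene, and with voom Trim9 (0.0589) and Ankrd1 (0.0633). DESeq2 called 94 genes, all 23 of these among them.

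Immediate early genes were the list with the smallest p in Gastroc (higher, adjusted p = 9.13e-13, adjusted p = 0.230 with an estimated correlation); all 19 were above 0 and 9 passed when adjusted over the list alone. Stress genes were higher (adjusted p = 6.74e-07, adjusted p = 0.230 with an estimated correlation), with 3 of 16 past over all genes and 5 adjusted over the list alone. The slow fibre list did not pass (adjusted p = 0.642), and its members went both ways: adjusted over the list alone Csrp3 and Mb rose and Myl3 and Tpm3 fell. Markers of other tissues moved beside these groups. Cartilage and bone genes (adjusted p = 0.00699) and tendon genes (adjusted p = 0.0126) were higher, both with adjusted p = 0.833 with an estimated correlation. Endothelial genes (adjusted p = 0.000533, adjusted p = 0.230 with an estimated correlation; Cdh5, Cldn5 and Tek fell when adjusted over the list alone) and macrophage genes (adjusted p = 0.000677, adjusted p = 0.515 with an estimated correlation) were lower. The cartilage call ended without KO column 0 (adjusted p = 0.109), KO column 1 (0.0684) or WT column 1 (0.0853), and the tendon call without KO column 0 (0.108) or WT column 1 (0.417). Without both KO columns 0 and 1 the macrophage (0.246), tendon (0.246) and cartilage calls (0.621) ended, and proliferation (0.0316) and liver genes (0.0236) were lower. The number of lists past the test was 4 without either of KO column 0 and WT column 1, against 6 with all libraries. The other 20 lists did not pass; differentiation genes had an adjusted p of 0.941, and developmental isoforms and FGF feedback genes came nearest (0.201 each). Median, mean and test differed in sign for other myosins, fibroblast, liver, skin and both Hox lists.

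In Dia the stress genes rose as a group, with Ankrd2 as the 1 gene past the test. Ankrd2 (chromosome 19, 42036038 to 42045110) was at 264 ± 64.9 CPM in KO and 98.1 ± 17.3 CPM in WT, a log2 change of 1.43 ± 0.17 (adjusted p = 0.0142; 6 of 6 KO samples above the WT median). It was the 1 gene of 14487 called by edgeR, against 604 with an unadjusted p under 0.05, 29 genes by DESeq2 and 2 by limma voom with quality weights. Csrp3 (0.99 ± 0.14) and Btg2 (1.05 ± 0.16), both at adjusted p = 0.0635, came next, then Chst5 (-1.39, adjusted p = 0.154) and Pdxk (0.54, adjusted p = 0.157). Atp9a (-0.47) and Trib1 (0.72) followed, both at adjusted p = 0.253. Ankrd2 kept its call without KO column 0, 1 or 4 or WT column 0. Without KO columns 2, 3 and 5 it had adjusted p = 0.0705, 0.0677 and 0.0759. Without WT columns 1 to 5 it had 0.0864, 0.0889, 0.0747, 0.0820 and 0.0827. In the fit of all 48 libraries it had adjusted p = 0.272. The count was 4 without KO column 4. On simulated data, which had no structure among the libraries of a group, the fit found 59.7% of genes changed 2-fold in Dia.

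The stress list was higher in Dia with the preset correlation (adjusted p = 1.55e-10) and with an estimated one (adjusted p = 0.00469); adjusted over the list alone Ankrd2, Csrp3, Ankrd1, Foxo1 and Mstn rose. Immediate early genes were higher (adjusted p = 1.03e-11, adjusted p = 0.179 with an estimated correlation), with Btg2 past when adjusted over the list alone. Slow fibre genes were lower (adjusted p = 0.00948, adjusted p = 0.693 with an estimated correlation): adjusted over the list alone Myl3 and Tpm3 fell and Csrp3 rose. Tendon genes were lower (adjusted p = 7.27e-07, adjusted p = 0.149 with an estimated correlation; Kera fell when adjusted over the list alone), as were fibroblast genes (adjusted p = 0.00206, 0.693). Glycolysis genes (adjusted p = 0.00948) and neuromuscular junction genes (adjusted p = 0.0119) were lower, both with adjusted p = 0.626 with an estimated correlation, and proliferation genes were higher (adjusted p = 0.0119, 0.805). The direction of the proliferation list turned without KO columns 0 and 1 (adjusted p = 0.457), and fast fibre (0.00700) and erythroid genes (0.00212) were then lower. The remaining 18 lists did not pass, and for liver genes the median was 0.60 while the test had the sign of a decrease. Median, mean and test also differed in sign for fast fibre, other myosin, FGF feedback, cartilage, erythroid and adipocyte genes.

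Single libraries ended list calls in Dia as well. The slow fibre list had adjusted p = 0.154 without KO column 3, 0.0562 without WT column 0 and 0.0583 without WT column 5. The proliferation list had 0.722 and 0.168 without KO columns 0 and 1 and 0.186 and 0.162 without WT columns 4 and 5. The junction list had 0.0725 without KO column 3 and 0.0974 without WT column 0. The glycolysis list had 0.121 without KO column 3, 0.0562 without WT column 0 and 0.101 without WT column 3, and the fibroblast list 0.0984 without KO column 4. Without KO column 4 10 lists passed and without WT column 1 12 did, against 8 with all libraries.

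**Figure D3:**
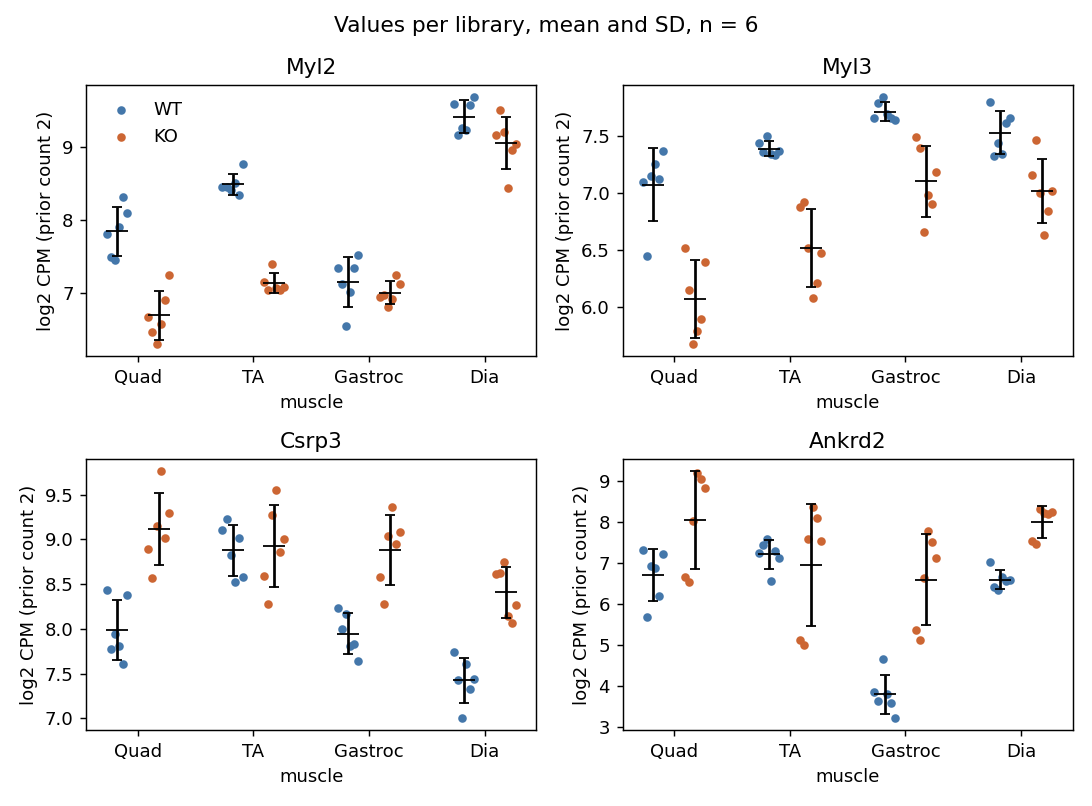
Log2 CPM (prior count 2) of Myl2, Myl3, Csrp3 and Ankrd2 in each library by muscle and genotype, with the mean and SD of 6 libraries; the vertical axes do not start at 0. Myl2 in TA (140 CPM in KO, 359 CPM in WT) and Ankrd2 in Gastroc (120 and 14.5 CPM) did not overlap between genotypes.

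Across muscles, Myl2 had the smallest p in the test of equal KO effects. The test of equal effects passed for 2 of 15090 genes, Myl2 (adjusted p = 0.00788) and Ces5a (adjusted p = 0.0256). DESeq2 called 8 genes, with only 1 of these 2 among them. Of 50 regroupings of the libraries 3, the real one included, called as many, so chance was not excluded, and the libraries of 1 animal were treated as independent. In that joint fit Myl2 changed by -1.16 ± 0.15 in Quad, -1.36 ± 0.15 in TA, -0.17 ± 0.15 in Gastroc and -0.34 ± 0.15 in Dia. Ces5a changed by 0.37, -0.83, 1.85 and 0.47 in the same order. Of the 6 pairs of muscles only TA and Gastroc had genes past the test of the pair, 2 in number. The count fell to 1 without any of KO columns 0, 1 and 2 or WT columns 0, 2 and 4 of TA, KO columns 3, 4 and 5 or WT columns 0, 2, 3, 4 and 5 of Gastroc, and it was 3 without KO column 3 of Dia. Ankrd2 was called in Gastroc and in Dia, and the other 36 of the 37 genes called anywhere were called in 1 muscle, which by itself does not show that their effects differed.

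With all 48 libraries in 1 additive model, the slow fibre genes Tpm3 and Myl3 fell and the immediate early gene Btg2 rose with the smallest p-values. No list was tested in this fit, and most of the other named genes are in no list. Tpm3 changed by -0.44 ± 0.05, Myl3 by -0.73 ± 0.08 and Btg2 by 0.77 ± 0.08, each with adjusted p = 8.94e-09, and Myl2, which passed the test of equal effects, by -0.76 ± 0.11 (adjusted p = 2.61e-06). Pde4d (0.78), Trib1 (0.56), Camta1 (0.44), Nfil3 (0.63), Cebpb (0.82), Ccrn4l (0.69), Adamts15 (0.50), Adamts1 (0.39) and Mn1 (0.65) rose. Ebf2 (-0.36), Cyb561d1 (-0.55), Tspan18 (-0.29), the macrophage gene Spi1 (-0.43), Tpst1 (-0.41), Fmnl3 (-0.22) and Prcp (-0.23) fell. In all 750 genes were higher and 403 lower of 15090. The libraries of 1 animal are not independent and could not be summed, so these p-values are too small. Without KO columns 0 and 1 the count was 4698.

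The KO effects were correlated across genes between muscles. Over 13800 genes Pearson's r (Spearman's rho) was 0.698 (0.650) for Quad and Gastroc, 0.598 (0.548) for Quad and TA and 0.506 (0.446) for Quad and Dia. It was 0.504 (0.494) for TA and Gastroc, 0.430 (0.373) for Gastroc and Dia and 0.378 (0.348) for TA and Dia. Genes are not independent replicates, so the values were set beside 100 permutations of the genotypes within each muscle. The adjusted permutation p was 0.0396 for Quad and Gastroc, Quad and Dia, and TA and Gastroc, 0.0475 for Quad and TA, 0.0446 for Gastroc and Dia, and 0.0693 for TA and Dia. The permutations moved libraries in each muscle separately and so do not keep deviations that the muscles of 1 animal share, which makes these p-values too small.

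In wild-type libraries the diaphragm differed from the 3 limb muscles in Hox genes, in adult fast myosin genes and in mesothelial and liver genes. Posterior Hox genes and Tbx4 were lower, with Hoxc10 at -8.13 ± 0.29, Hoxa10 at -6.31, Hoxa9 at -5.27 and Tbx4 at -2.67, and anterior Hox genes were higher, with Hoxb3 at 3.18 and Hoxa5 at 2.04. The adult fast myosin genes Myh1 (3.12) and Myh4 (2.82) were higher. So were Mb (4.39 ± 0.10), Myl2 (1.62) and Myh7 (1.23) of the slow fibre list and the atrophy genes Trim63 (3.04) and Fbxo32 (3.44). Myl4 (-1.30), Chrng (-1.88), Myog (-1.39) and Myod1 (-1.40) were lower, but the differentiation list (adjusted p = 0.110), the progenitor list (0.0683), the slow fibre list (0.0667) and the stress and atrophy list (0.0518) held members of both directions and did not pass. The mesothelial gene Msln was at 122 ± 16.1 CPM against 0.653 to 0.720 CPM in the limb muscles. Liver genes were higher (Alb 7.74 ± 0.44, Afp 7.78, Fga 7.92), with Alb at 1318 ± 1041 CPM. The liver and mesothelium lists stand for tissues that a dissected muscle could hold. Alb ran from 192 to 3033 CPM over the WT and from 15.3 to 5836 CPM over the KO diaphragm libraries. An even level in the diaphragm itself would not give this spread. Beyond that, RNA carried over from such tissue could not be told apart from that of the diaphragm. Of 14831 genes 1038 were higher and 524 lower by at least 2-fold at an adjusted p of 0.05, and in the KO libraries the same contrast gave 1495 in all.

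By list, with the number of measured genes past 0.05 at 2-fold, the lower groups in diaphragm were posterior Hox (7 of 8, adjusted p = 8.64e-08), proliferation (8 of 22, adjusted p = 1.94e-11), FGF feedback (adjusted p = 0.00172), cartilage (0.00730), tendon (0.00747), developmental isoforms (0.0188), Schwann cell (0.0344) and fibroblast genes (0.0499). The higher groups were oxidative phosphorylation (2 of 17, adjusted p = 1.94e-11), liver (9 of 9, adjusted p = 5.97e-08), fast fibre (5 of 17, adjusted p = 1.38e-05), anterior Hox (7 of 13) and mesothelium (4 of 4), both at the same value, erythroid (adjusted p = 0.000125), glycolysis (0.00401), endothelial (0.00527) and macrophage genes (0.0188). With an estimated correlation the posterior Hox (adjusted p = 0.00741), anterior Hox (0.00548) and mesothelium lists (0.00828) still passed and no other list did; the proliferation list had 0.0705 and the oxidative list 0.0933.

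Among the 3 wild-type limb muscles 3086 of 14625 genes differed, with the highest level in Quad for 572, in TA for 1287 and in Gastroc for 1227. Col9a1 was highest in Quad, at 47.9 ± 28.5 CPM, with 0.601 CPM in TA and 8.24 CPM in Gastroc, and so was Col2a1 at 744 ± 401, 81.0 and 150 CPM. Alx4 was also highest there (15.5 CPM against 4.61 and 1.81). TA was highest for Ankrd2 (170 CPM, with 117 in Quad and 14.6 in Gastroc), Tbx1 (52.6, 23.9 and 4.38 CPM), Myh4 (136, 81.8 and 15.9 CPM) and Lmx1b. Gastroc was highest for Barx2 (14.1 CPM against 4.97 in Quad and 1.82 in TA), Meis2 and Hoxd9. Ankrd2, Xirp2 and Mapt, which rose in KO Gastroc, were lowest in wild-type Gastroc of these muscles, with Mapt at 3.26 CPM there and 22.7 CPM in TA. The same wild-type Gastroc libraries serve in both comparisons, so low values there feed both. Whether this holds for the other genes that rose in Gastroc was not tested.

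In the authors' tables, DESeq2 adjusted p-values were under 0.05 for 72 genes in Quad (55 higher, 17 lower), 108 in TA (72 and 36), 95 in Gastroc (70 and 25) and 28 in Dia (22 and 6). Myh3 was among those in TA, with a log2 ratio of -0.32 (adjusted p = 0.0406). Every gene called by edgeR, 14 in TA, 23 in Gastroc and 1 in Dia, was among them. Their shorter lists, cut at an adjusted p of 0.10 with a minimum change, held 10, 9, 19 and 5 genes. None of the 10 in Quad passed edgeR at 0.05: Myl2, Shisa3, Myl3, Csrp3, Ppargc1a, Btg2, Trim63, Foxred2, Dusp5 and Lpin1. Fam107a of the TA list, Stmn4 and Mtus2 of the Gastroc list and Csrp3, Btg2, Maff and Arl4d of the Dia list did not pass at 0.05 either. At 0.10 in edgeR only Dusp5 and Lpin1 in Quad (adjusted p = 0.121 each) and Maff (0.309) and Arl4d (0.443) in Dia did not pass. Across genes their log2 ratios and those of edgeR had a correlation of 0.907 in Quad, 0.925 in TA, 0.919 in Gastroc and 0.862 in Dia. Their test of exon use passed for 53, 14, 34 and 12 genes, and no exon value was given for Myh3.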

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

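Dixon's test was run on the totals and on log2 CPM of the named genes in 470 groups of 6 libraries, and 27 groups passed, where about 1 in 20 would by chance. In Quad these were Myl3 in WT (ratio 0.709; column 1 low at 87.4 CPM, the others 137 to 165), Ankrd1 in KO (0.640; column 3 high at 152 CPM), Cldn5 in KO (0.631; column 5 high at 43.6 CPM) and Cdh5 in WT (0.641; column 5 high at 318 CPM). In TA they were Myl2 in KO (0.681; column 2 high at 168 CPM, the others 131 to 142) and in WT (0.630; column 5 high at 435 CPM), Lpin1 in KO (0.714; column 3 high at 123 CPM), Mylk2 in WT (0.741; column 2 low at 153 CPM), Myh7 in KO (0.674; column 3 low at 489 CPM), Cars in WT (0.650), Myh6 in KO (0.657) and Myf6 in WT (0.687). The Myl2 values were still without overlap between genotypes.

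In Gastroc the test passed for Ces5a in WT (0.656; column 3 low at 0.313 CPM), Cebpb in KO (0.628; column 3 high at 41.4 CPM), Trim63 in WT (0.667), Cldn5 in KO (0.788; column 5 high at 53.9 CPM), Chad in KO (0.721; column 5 low at 0.801 CPM, the others 4.55 to 8.62) and Acan in KO (0.6251; column 5 low at 15.4 CPM). In WT Thbs4 (0.666; column 1 low at 295 CPM, the others 490 to 633), Mkx (0.637; column 1 low at 4.74 CPM) and Col11a2 (0.660; column 1 low at 47.1 CPM) passed. Without WT column 1 of Gastroc the tendon list no longer passed there (adjusted p = 0.417). In Dia it passed for Klf6 in KO (0.797; column 5 low at 156 CPM) and Colq in WT (0.642). Among totals it passed for WT Quad (0.636), WT Gastroc (0.677), KO Dia (0.708) and WT Dia (0.819).

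In the test of equal effects over the 4 muscles Myl2 (adjusted p = 0.00788) and Ces5a (adjusted p = 0.0256) passed. DESeq2 called only 1 of these 2. As many genes were called in 3 of 50 splits, the real one included, so chance was not excluded.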

How the results depend on the processing

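The tests without KO columns 0 and 1 were chosen after the result was seen. The number of genes past the test in Quad (0) was 8 with upper-quartile factors, 71 with DESeq2, 16 with limma voom and quality weights, 7 without a filter, 16 with all 48 libraries in 1 fit, 13 at an adjusted p of 0.10 and 10 with a minimum change as well, 6 with a sex covariate, 25 with 1 surrogate variable and 133 without KO columns 0 and 1. In TA (14) it was 117 with DESeq2, 26 with voom, 22 at 0.10, 8 with the sex covariate, 50 with the surrogate variable and 219 without KO columns 0 and 1. In Gastroc (23) it was 94, 36 with all 48 libraries, 37 at 0.10, 51 with the surrogate variable and 108 without these columns. In Dia (1) it was 29 with DESeq2, 2 with voom, 30 with all 48 libraries (0 shared), 3 at 0.10 with or without the minimum change, 2 with the sex covariate, 3 with the surrogate variable and 72 without these columns. The equal-effects test (2) gave 8 with DESeq2, the shared model (1153) gave 1892 at 0.10 and 4698 without KO columns 0 and 1, and diaphragm against limb (1562) gave 8456 without the fold threshold. The cause was not tested.

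Myh3 in TA changed by -0.37 with DESeq2 (adjusted p = 0.0368; 0.0741 to 0.446 in the other alternatives), and in Quad by 0.0118 with the sex covariate, a turned sign. Signs also turned for Myh4 in TA with voom (0.018), Krt10 in diaphragm against limb in KO libraries (-0.165), Cdkn1c in Gastroc without KO columns 0 and 1 (-0.0455), Myh6 in Dia without KO column 3 (-0.111, and up to 1.52 without KO column 2) and the proliferation list in Dia without KO columns 0 and 1 (p 0.457). Of the lists past the test in Dia, Gastroc, Quad and TA (8, 6, 7 and 3), 1, 0, 0 and 1 were left with an estimated correlation and 1, 0, 0 and 1 with fry in one direction. With fry in either direction 3 passed in Dia and 1 in TA, and several passed in Quad and Gastroc. Among these were slow fibre genes (fry adjusted p = 4.69e-05 in Quad and 9.82e-07 in Gastroc), stress genes (0.0151 and 0.00242) and immediate early genes (0.0175 and 0.0224). Without KO columns 0 and 1 there were 4 lists in Quad and 7 in TA, and proliferation genes were lower in Quad, TA and Gastroc (adjusted p = 0.0221, 9.26e-05 and 0.0316). Over the more abundant genes the effect correlation was 0.713 for Quad and TA, 0.837 for Quad and Gastroc, 0.677 for Quad and Dia, 0.589 for TA and Gastroc, 0.470 for TA and Dia and 0.568 for Gastroc and Dia. Of 6548 alternatives, 6119 concerned single values, of which 5630 were unchanged, 254 weaker, 230 stronger and 5 turned. The other 429 concerned main values such as numbers of calls, of which 320 were unchanged.

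With each library left out in turn the counts ran from 0 to 2 in Quad, 4 to 26 in TA, 4 to 29 in Gastroc, 0 to 4 in Dia, 1 to 3 for equal effects, 918 to 1337 for the shared model, 1539 to 1604 for diaphragm against limb and 2619 to 3135 among limb muscles. Lists ran from 4 to 12 in Quad, 3 to 7 in TA, 4 to 8 in Gastroc and 6 to 12 in Dia. Myh3 ran from -0.0505 to 0.0505 in Quad, -0.43 to -0.32 in TA, 0.07 to 0.16 in Gastroc and 0.36 to 0.57 in Dia. No paired analysis was possible because the columns carry no replicate or animal number. Libraries without Xist under KO columns 2 and 3 in all 4 muscles hint at shared animals, but groups were not drawn from the data, and the test of equal effects takes the 48 libraries as independent. Not run for that reason were the replicate block, sums per animal, duplicateCorrelation, the mean of log2 CPM per animal, and splits with replicates so that no animal is shared.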

Other observations

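Genes of sex were readable in every library. Xist was absent from 2 KO libraries and 1 WT library of each muscle, KO columns 2 and 3 in all 4 muscles and WT column 1 in TA, Gastroc and Dia but WT column 0 in Quad. Equal column numbers therefore do not always mark 1 animal.

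The tests of sex, of other tissues, of litter and of fewer slow fibres were chosen after the result was seen, and the lists of fasting and heart genes were added then. KO columns 0 and 1 held more RNA of liver genes and lay apart from the other KO libraries. In 0 muscles were they the 2 lowest or 2 highest totals of the KO group, which argues against sequencing depth. In 3 muscles KO columns 4 and 5, also with Xist, lay on the other side, which argues against sex. The surrogate variable fitted without genes of other tissues had a correlation of at least 0.992 with the original, but only short lists of markers were removed, so RNA of other tissues is not excluded. A litter or batch remains possible and could not be tested, as 0 samples have labels that name one.

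The stress genes were higher in each muscle with the preset correlation, but with an estimated one only in Dia (adjusted p = 0.00469, against 0.247 in Quad, 0.592 in TA and 0.230 in Gastroc), and the sources do not say how long each muscle waited before freezing. With a covariate for immediate early genes the list kept most of its median log2 change in 4 muscles. It was 0.37 in Quad, 0.22 in TA, 0.26 in Gastroc and 0.59 in Dia, against 0.37, 0.23, 0.27 and 0.46 without the covariate. The covariate was itself higher in KO, by 0.50, 0.30, 0.52 and 0.48, and in TA the camera p with it was 0.0466. As far as the preset correlation holds, these values argue only against handling that moves in step with immediate early genes as the whole cause. Without KO columns 0 and 1, and without the covariate, the median was 0.48 in Quad, 0.38 in TA, 0.42 in Gastroc and 0.46 in Dia. Thinning all libraries to 1 total left the call with the preset correlation in 4 muscles, which argues against depth. A fasting response could not be told apart: the fasting list was higher with an estimated correlation in 0 muscles (p = 0.150, 0.0522, 0.228 and 0.106), against p = 9.66e-05, 7.34e-07, 0.00109 and 4.44e-05 with the preset one.

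The lower slow fibre genes in TA might reflect fewer slow fibres; in Quad the list was lower only with the preset correlation (adjusted p = 0.483 with an estimated one, 0.0612 without KO columns 0 and 1). The log2 ratio of Myl2 to Myh7 was lower in KO in 2 muscles, by -0.72 in Quad and -0.83 in TA (exact adjusted p = 0.00433 in both), and not in Gastroc (-0.33, 0.0952) or Dia (-0.28, 0.139). Myl2 was picked as the gene with the smallest p, so the ratio restates its fall and fewer slow fibres are not excluded. Heart RNA in the wild-type libraries was tested with 3 measured genes of 11, Tnnt2 (-0.08), Ryr2 (-0.06) and Tnni3 (0.04), with a median of -0.0611 in TA. Ryr2 (1.07 CPM in KO, 1.12 in WT) and Tnni3 (2.27 and 2.21 CPM) were near the floor. Tnnt2 was at 238 and 252 CPM, a level that could hide a small share of heart RNA. These 3 genes showed no clear change, but heart RNA is not excluded. Myh2 lies beside Myh3, and in 0 muscles did the genes within 1 Mb pass 95% of random windows (percentiles 93.2, 75.3, 58.0 and 91.7), so an effect on the neighbourhood could not be told.

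Regroupings of the libraries asked how many genes chance alone calls. In TA 4 of 100 splits, the real one included, called as many genes (highest other 693), and in Gastroc 2 of 100 did (318). In diaphragm against limb 1 of 100 did (525) and among limb muscles 1 of 100 (196). Each of these shares was under 0.05, which makes chance less likely but does not exclude it. In TA the share was close to that limit. The wild-type splits moved libraries between muscles and do not keep the libraries of 1 animal together. In Dia 8 of 100 splits called as many genes (147) and for equal effects 3 of 50 (180), so there the share was not under 0.05. In Quad 100 of 100 did (398), which the real count of 0 makes certain, so these splits say nothing on chance there. For the shared model 1 of 50 did (highest other 0), but these splits moved libraries within each muscle and do not exclude chance over animals. What set apart the splits with several times the real count was not tested.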
